A study of Mus musculus with 6 samples.

How the data were processed

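Whole-liver RNA from 3 Lmln-KO and 3 WT mice was measured by paired-end RNA sequencing after ribosomal RNA depletion with a directional library kit, per the labels' protocols. The deposited values are whole-number counts of reads per gene name, not normalized; per the file headers the authors made them with featureCounts 2.0.1 over exons of the Ensembl release 102 annotation of GRCm38. The submitters' processing notes name Subread 2.0.2, featureCounts and edgeR 3.36.0. The header's command line gives neither the paired-end nor the strand option, so the reads of a pair were counted singly and antisense partners cannot be told apart, and it gives no option for reads that map to several places or overlap several genes. The aligner is not given in the sources used here. The labels do not give sex.

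The table held 55367 gene names, 21412 of them without a count, and 0 rows that named no gene. All 6 columns of counts were assigned by the library names in the titles. Every pair of libraries differed by far more than sampling noise (chi-square per degree of freedom of at least 10.9), so each was used as 1 replicate. The labels number replicates but do not say in so many words that each came from its own animal. P-values of the gene tests measure the spread between these libraries.

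Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with its default minimum count of 10 (18703 genes, which hold 99.8% of counts), a robust quasi-likelihood fit on genotype, and Benjamini-Hochberg adjustment at 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Levels are TMM-normalized CPM computed from the deposited counts. Differences within a sex-marker set are differences of mean log2 CPM with a prior count of 2. Gene lists were fixed before the data were examined. There were 45, of which 42 had at least 5 tested genes. The replication-dependent histones matched 0 gene names in the table, the Y-linked list has 4 genes, and the adipocyte, pancreas and gallbladder list had 3 tested. Lists were tested with camera in limma 3.58.1 on log2 CPM at a preset correlation of 0.01, with an estimated correlation, and with fry. At the preset correlation camera compares a list's genes with the other tested genes, so its precision comes largely from the number of genes. Its p-value there does not measure the spread between libraries. With an estimated correlation camera takes its degrees of freedom from the few libraries. A list can then lose its call without a high correlation between its members. Fisher's exact tests near Lmln likewise count genes. Of the lists, those for hepatocyte, endothelial, cholangiocyte, neutrophil, erythrocyte, interferon, acute phase, heat shock, unfolded protein response, oxidative phosphorylation, mitochondrial mRNA, circadian, insulin and IGF, bile acid, xenobiotic, NRF2, autophagy, iron, amino acid and liver cancer genes did not pass in the fit by genotype (camera adjusted p between 0.0565 and 0.978).

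The rule for named genes, also fixed before the data were examined, took Lmln and up to 12 higher and 12 lower genes that passed the threshold. Since none passed, it took the genes with the smallest p until 20 were named, among genes with an average log2 CPM of at least 1, an official symbol and no overlap between the groups. For each list up to 4 members with the smallest p could be named.

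Alternatives fixed beforehand were other scalings, DESeq2 1.42.0, limma-voom with and without quality weights, other filters, the replicate number as a block, leaving out each library, leaving out sex-linked and sex-biased genes, and a fold-change threshold. A term for the sex-chromosome transcripts in a library (Xist above or below the summed Y-linked genes) was added after the data were examined. That split was used to adjust and to show within-set values, never as a comparison of its own.

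The steps were tested on simulated counts drawn from the libraries' means and dispersions, with 200 changed genes. A further 20 genes were shifted 1.5-fold as a list, and the shares of calls below leave them out. The draws were not repeated. By genotype alone edgeR recovered 28% of 100 genes changed 2-fold and 74% of 100 changed 4-fold, among 18252 genes tested, with 12 further unchanged genes (10.5% of the calls). DESeq2 recovered 49% and 86%, with 54 further unchanged genes (28.6% of the calls). With the sex-marker term, among 18310 genes, edgeR recovered 49% and 85% with 19 further genes (12.4%), and DESeq2 51% and 82% with 28 further genes (17.4%). Both tools therefore exceeded the nominal 5% in this simulation, DESeq2 by more. Simulated genes vary independently, unlike those in the real libraries.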

Results

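RNA sequencing of whole liver was compared between mice carrying a homozygous disruption of Lmln (Lmln-/-, here Lmln-KO) and wild-type (WT) mice of the C57BL/6J strain, with 3 libraries in each group. Lmln encodes invadolysin, a metalloprotease known to localise to lipid droplets. Gene counts summed to 20957895, 21915466 and 22494696 in Lmln-KO replicates 1, 2 and 3 and to 17388360, 18272045 and 17397960 in WT replicates 1, 2 and 3, so the Lmln-KO libraries were the deeper ones. Of 55367 gene names, 18703 had enough counts to be tested. The animals were 46 weeks old, except that the animal of Lmln-KO replicate 3 was 39 weeks old.

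The targeted gene was low in every Lmln-KO library. Lmln (chromosome 16, 33062521 to 33127695, GRCm38) had 4, 12 and 2 counts in Lmln-KO replicates 1, 2 and 3, and 79, 80 and 39 counts in WT replicates 1, 2 and 3. Its normalized level was 0.281 ± 0.253 CPM in Lmln-KO and 3.74 ± 1.31 CPM in WT (SD, n = 3), a log2 fold change of -3.72 (SE 0.582). The groups did not overlap, but edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.933, against 2.3e-06 with DESeq2. Counting took no account of strand, and the predicted gene Gm17106 overlaps Lmln.

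The libraries also differed in sex-chromosome transcripts, which the labels do not mention. Xist, the RNA that coats the inactive X chromosome, reached 1947 CPM in Lmln-KO replicate 3 and 1884 and 1878 CPM in WT replicates 2 and 3, and lay below 1 CPM in the others. In Lmln-KO replicates 1 and 2 and WT replicate 1, 4 Y-linked genes summed to 216, 235 and 230 CPM, and they were near 0 in the libraries with Xist. The Lmln-KO group thus held 2 libraries with Y-linked transcripts and 1 with Xist, and the WT group held 1 and 2. The first principal component, with 56.3% of the variance, parted the libraries in this way and not by genotype. Lists that passed by genotype alone are therefore given also with a term for this difference (the sex-marker term, added after the data were examined) and as medians within each of the sets. Each set holds 1 genotype by a single library. With Y-linked transcripts that is WT replicate 1. With Xist it is Lmln-KO replicate 3, from the 39-week-old animal.

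**Figure D1:**
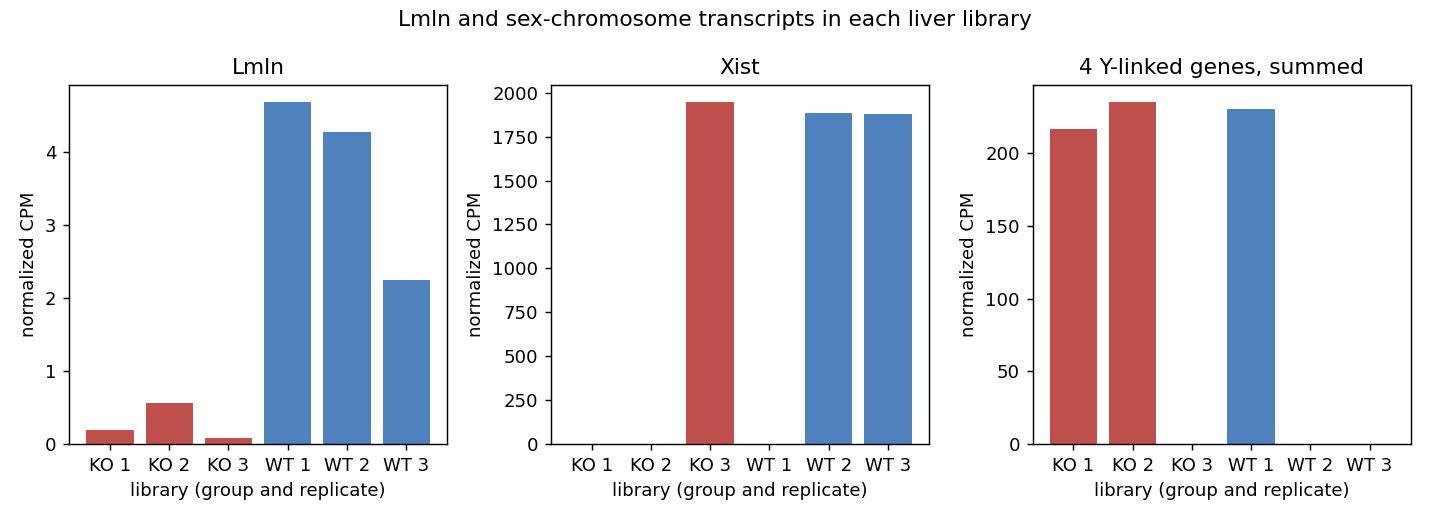
Normalized CPM (bars, linear axes from 0) of Lmln, of Xist and of 4 summed Y-linked genes in each of the 6 libraries, red for Lmln-KO and blue for WT. Lmln lies between 0.0853 and 0.567 CPM in Lmln-KO and between 2.25 and 4.69 CPM in WT, while Xist and the Y-linked genes divide both groups.

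The comparison of genotypes asked which liver transcripts differ when Lmln is disrupted. No gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test: 0 of 18703 genes were called, 871 had an unadjusted p under 0.05 (284 higher and 587 lower in Lmln-KO), and 935 would be reached by chance. DESeq2 called 24 genes, all lower in Lmln-KO, and limma-voom called 0. When the sex-marker term was included, edgeR called 1 gene, Ppp1r3g, and DESeq2 called 31, of which 27 were lower and 4 higher. Of the DESeq2 calls, 16 were shared by the fits with and without the term. Among tested genes, 10.3% showed no overlap between the groups, where chance gives 10%.

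The 20 genes named by the smallest p were all lower in Lmln-KO, and none passed in the edgeR fit by genotype alone (adjusted p 0.933 for each). Ppp1r3g (chromosome 13, 35958839 to 35970388), a subunit that directs protein phosphatase 1 to glycogen, measured 0.647 ± 0.589 CPM in Lmln-KO (SD, n = 3) and 9.56, 18.1 and 32.3 CPM in WT replicates 1, 2 and 3 (SD 11.5). Its log2 fold change was -4.91 (SE 0.78) and, with the sex-marker term, -4.51 (SE 0.329), with an edgeR adjusted p of 0.0179. The difference was -4.58 within the libraries with Y-linked transcripts and -4.09 within those with Xist. That call was lost when Lmln-KO replicate 1, 2 or 3 or WT replicate 1 was left out of the fit with the term (adjusted p 0.159, 0.205, 0.269 and 0.281), with log2 fold changes of -4.36, -4.50, -4.92 and -4.25. It held without WT replicate 2 or 3 (adjusted p 0.000218 and 0.00255). DESeq2 called Ppp1r3g without and with the term (adjusted p 1.77e-05 and 4.73e-29). The predicted gene Gm30127 overlaps Ppp1r3g.

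**Figure D2:**
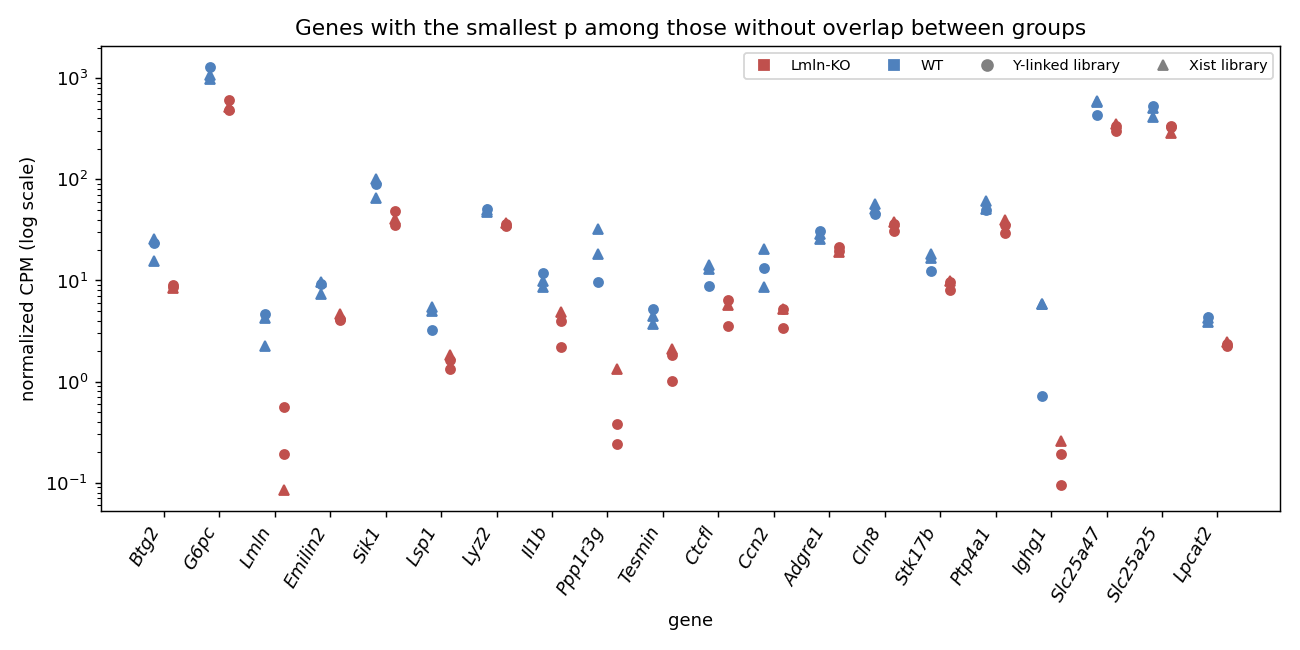
Normalized CPM (log axis) of the 20 named genes in each library, with red for Lmln-KO, blue for WT, circles for libraries with Y-linked transcripts and triangles for libraries with Xist. The values of the groups do not overlap for any gene shown, which is how the genes were chosen.

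G6pc (chromosome 11, 101367561 to 101377903), the catalytic subunit of glucose-6-phosphatase, measured 541 ± 64.5 CPM in Lmln-KO and 1118 ± 155 CPM in WT (SD, n = 3), a log2 fold change of -1.05 (SE 0.162). The difference was -1.24 within the libraries with Y-linked transcripts and -0.98 within those with Xist. Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase, measured 2028 ± 494 against 3709 ± 1540 CPM, with a log2 fold change of -0.87, or -0.48 without WT replicate 3. Across the 30 tested genes of gluconeogenesis and glycolysis the median log2 fold change was -0.03 and the list did not pass (camera adjusted p 0.285). In edgeR 1 gene was called when adjusted over the list alone and 0 over all genes tested. The list passed as lower in 1 of 16 alternatives (camera adjusted p 0.0497), and its median ran from -0.11 to -0.0004 over them. DESeq2 called G6pc over all genes, with an adjusted p of 2.3e-06 and, with the sex-marker term, 4.32e-09.

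Immediate early genes, which respond rapidly to stimuli, fell as a list: 17 of 19 tested members had a negative log2 fold change, with a median of -0.50 and a camera adjusted p of 1.94e-06 at a preset correlation. This call was lost with an estimated correlation (adjusted p = 0.184). The estimate was -0.00482, below the preset 0.01, so a higher correlation between members was not the reason for the loss. The unadjusted camera p went from 9.25e-08 to 0.00439, on far fewer degrees of freedom. Fry's mixed test, which takes no account of direction, gave an adjusted p of 0.00338, or 0.00371 with the sex-marker term. Fry's directional test did not pass (adjusted p 0.204, or 0.326 with the term). Btg2, an antiproliferative transcriptional cofactor, measured 8.67 ± 0.266 CPM in Lmln-KO and 21.5 ± 5.23 CPM in WT (SD, n = 3). Egr1 and Fos, both transcription factors, had log2 fold changes of -1.28 (SE 0.351) and -1.21 (SE 0.379). With the sex-marker term the list's median was -0.56 (adjusted p 4.86e-09, and adjusted p = 0.504 with an estimated correlation). Without Lmln-KO replicate 2 it was -0.78 in the fit by genotype alone. Within the libraries with Y-linked transcripts it was -0.35, and within those with Xist -0.81. When adjusted over the list alone 2 genes passed in edgeR by genotype, against 0 over all genes tested. DESeq2 called Btg2 over all genes (adjusted p 3.33e-05, and 4.35e-05 with the sex-marker term), and Fos and Egr1 only with the term (adjusted p 0.00683 and 0.0297).

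Genes of lipid droplet proteins, the site at which invadolysin is found, did not pass: the median log2 fold change of 31 tested genes was 0.02 (camera adjusted p 0.416). Hilpda, a droplet protein induced by hypoxia, had a log2 fold change of -1.58 (SE 0.555), or -1.02 without WT replicate 3. Abhd5, a coactivator of triglyceride lipase, had one of 0.46 (SE 0.163), or 0.28 without Lmln-KO replicate 2. Lists for fatty acid and triglyceride synthesis (median 0.06, adjusted p 0.978), for fatty acid oxidation and PPARA targets (median -0.01, adjusted p 0.91) and for lipoprotein assembly, transport and fatty acid uptake (median -0.17, adjusted p 0.191) did not pass either. The oxidation list passed once the sex-marker term was included, with a median of 0.15 (adjusted p 0.0142), and not with an estimated correlation (adjusted p = 0.757). By genotype alone it passed as lower without Lmln-KO replicate 3 (median -0.25) and as higher without Lmln-KO replicate 1 (0.15) or WT replicate 2 (0.27). The median of the synthesis list was -0.08 with the term (adjusted p 0.0549), where 4 members passed in edgeR when adjusted over the list alone and 0 over all genes tested. By genotype alone it ran from 0.15 without WT replicate 1 to -0.10 without WT replicate 3 or Lmln-KO replicate 2. Lpin1 and Lpin2, phosphatidate phosphatases of that list, had log2 fold changes of -1.42 (SE 0.497) and -0.70 (SE 0.213), and DESeq2 called Lpin1 only with the term (-1.02, adjusted p 0.00683). DESeq2 also called the fatty acid desaturases Scd1 (-1.05, adjusted p 0.00214) and Scd3 (-1.67, adjusted p 0.0339) only with the term. These 2 genes are named after their values were seen.

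Cholesterol synthesis genes and SREBP2 targets rose as a list at the preset correlation, with 25 of 27 members positive, a median log2 fold change of 0.42 and a camera adjusted p of 1.24e-05, and not with an estimated correlation (adjusted p = 0.758). No member had an unadjusted p under 0.05. The median with the sex-marker term was again 0.42 (adjusted p 0.000261, and adjusted p = 0.739 with an estimated correlation). The median was -0.01 within the libraries with Y-linked transcripts and 0.83 within those with Xist, and it was 0.19 without WT replicate 3 (adjusted p 0.0299).

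B and plasma cell markers fell as a list at the preset correlation, with a median log2 fold change of -1.56 over 20 genes (adjusted p 5.13e-08), and the call was lost with an estimated correlation (adjusted p = 0.758). The median was -0.45 within the libraries with Y-linked transcripts and -1.82 within those with Xist, and -0.86 without WT replicate 3. It was -1.20 with the sex-marker term (adjusted p 2.4e-07, and adjusted p = 0.739 with an estimated correlation). Ighg1, an immunoglobulin heavy chain gene of a family whose members share reads, measured 0.181 ± 0.0813 CPM in Lmln-KO and 4.12 ± 2.95 CPM in WT (SD, n = 3), and DESeq2 called it without and with the term (adjusted p 2.82e-05 and 1.82e-05).

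Extracellular matrix and fibrosis genes had a median of -0.39 over 39 genes (adjusted p 3.83e-06, and adjusted p = 0.758 with an estimated correlation). Monocyte-derived and lipid-associated macrophage markers had a median of -0.25 (adjusted p 0.00211), and cytokines, chemokines and NF-kB targets one of -0.19 (adjusted p 0.00337). Both calls were lost with an estimated correlation (adjusted p = 0.758). The macrophage median was -0.14 without WT replicate 3, -0.60 without Lmln-KO replicate 1 and -0.50 without WT replicate 1, and the cytokine call was lost without Lmln-KO replicate 2 (adjusted p 0.102). In the fit with the sex-marker term the matrix, macrophage and cytokine medians were -0.27, -0.30 and -0.16 (adjusted p 4.24e-05, 0.0042 and 0.00783), and none of them passed with an estimated correlation (adjusted p = 0.739). Within the libraries with Y-linked transcripts they were -0.16, -0.10 and -0.22, and within those with Xist -0.34, -0.66 and -0.21. Il1b, a proinflammatory cytokine, had a log2 fold change of -1.44 (SE 0.285) and was called by DESeq2 without and with the term (adjusted p 0.00664 and 0.0192), and Lyz2, the macrophage lysozyme, one of -0.46 (SE 0.0899). Kupffer cell markers did not pass (median -0.12, adjusted p 0.295), although Adgre1, their surface marker F4/80, measured 20.1 ± 1.34 against 28.6 ± 2.72 CPM. DESeq2 called neither Lyz2 (adjusted p 0.13 without and 0.27 with the term) nor Adgre1 (adjusted p 0.335 and 0.187). The Kupffer list passed as lower in 1 of 16 alternatives (camera adjusted p 0.0346), over which its median ran from -0.17 to 0.09.

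Stellate cell and fibroblast markers had a median of -0.28 (adjusted p 0.00211), dendritic cell and MHC class II genes -0.72 (adjusted p 0.00413), and T and NK cell markers -0.64 (adjusted p 0.016). All 3 calls were lost with an estimated correlation (adjusted p = 0.758), and with the sex-marker term, where the medians were -0.17, -0.55 and -0.26 (adjusted p 0.162, 0.0549 and 0.101). They were also lost without WT replicate 3 (adjusted p 0.108, 0.0883 and 0.0948), the stellate call without Lmln-KO replicate 1 (adjusted p 0.1), and the T and NK call under the stricter filter on low counts (adjusted p 0.0553). Over all alternatives the stellate median ran from -0.43 to -0.14, the dendritic one from -0.96 to -0.39, and the T and NK one from -0.985 to -0.26. Within the libraries with Y-linked transcripts the stellate, dendritic and T and NK medians were -0.12, 0.03 and -0.01, against -0.11, -0.89 and -0.51 within those with Xist.

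Cell cycle and mitosis genes fell at the preset correlation, with 21 of 25 members negative and a median of -0.42 (adjusted p 0.000188), and not with an estimated correlation (adjusted p = 0.758). The median was -0.06 within the libraries with Y-linked transcripts and -0.61 within those with Xist. The list's mean log2 CPM was 0.991 in WT replicate 1, inside the Lmln-KO range of 0.899 to 1.01, and 1.36 and 1.82 in WT replicates 2 and 3. Without WT replicate 3 the median was -0.15. It was -0.33 with the sex-marker term (adjusted p 0.00101, and adjusted p = 0.739 with an estimated correlation). Mki67, a proliferation marker, measured 2.26 ± 0.425 against 7.49 ± 4.83 CPM, a log2 fold change of -1.72, or -1.10 without WT replicate 3.

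Periportal hepatocyte genes had a median of -0.34 (adjusted p 0.00183) and pericentral ones a median of 0.17 (adjusted p 0.0297), and neither passed with an estimated correlation (adjusted p = 0.758). The periportal call was lost without WT replicate 3 (median -0.13, adjusted p 0.181). The pericentral call was lost without Lmln-KO replicate 3 (median 0.01), WT replicate 1 (0.13) or WT replicate 3 (0.06), and its median was 0.38 without WT replicate 2. With the sex-marker term the periportal and pericentral medians were -0.45 and 0.26 (adjusted p 0.00101 and 0.000252), and neither passed with an estimated correlation (adjusted p = 0.739). They were -0.25 and 0.11 within the libraries with Y-linked transcripts and -0.50 and 0.40 within those with Xist. P53 targets and senescence genes had a median of -0.26 (adjusted p 0.0298) and cytosolic ribosomal proteins one of 0.05 (adjusted p 0.0206), again lost with an estimated correlation (adjusted p = 0.758). These calls did not hold with the sex-marker term, where the medians were -0.17 and 0.03 (adjusted p 0.11 and 0.151). They were -0.23 and 0.06 within the libraries with Y-linked transcripts and -0.08 and 0.02 within those with Xist. The p53 call was lost without Lmln-KO replicate 1 or 2 or WT replicate 2 (medians -0.19, -0.20 and -0.05), and the ribosomal call without Lmln-KO replicate 2 or WT replicate 2 (medians 0.03 and 0.0022).

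Male-biased liver genes were higher in Lmln-KO, all 21 of them, with a median log2 fold change of 1.22 (adjusted p 0.000266), and female-biased genes were lower in 22 of 24 cases, with a median of -0.92 (adjusted p 0.00821). The calls were lost with an estimated correlation (adjusted p = 0.758 and 0.814). With the sex-marker term the medians were 0.37 (adjusted p 0.000755) and 0.07 (adjusted p 0.323), so the female-biased list no longer passed, and the male-biased one did not with an estimated correlation in that fit (adjusted p = 0.504). Within the libraries with Y-linked transcripts the medians were 0.37 and 0.05, and within those with Xist 0.24 and 0.07. By genotype alone the female-biased call was lost without Lmln-KO replicate 1 or 2 or WT replicate 2 or 3 (medians -0.34, -0.35, -0.41 and -0.40), and its median was -5.43 without Lmln-KO replicate 3 and -1.48 without WT replicate 1. The male-biased call was lost without WT replicate 2 (adjusted p 0.0679), and its median ranged from 0.76 to 4.28, the latter without WT replicate 1.

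**Figure D3:**
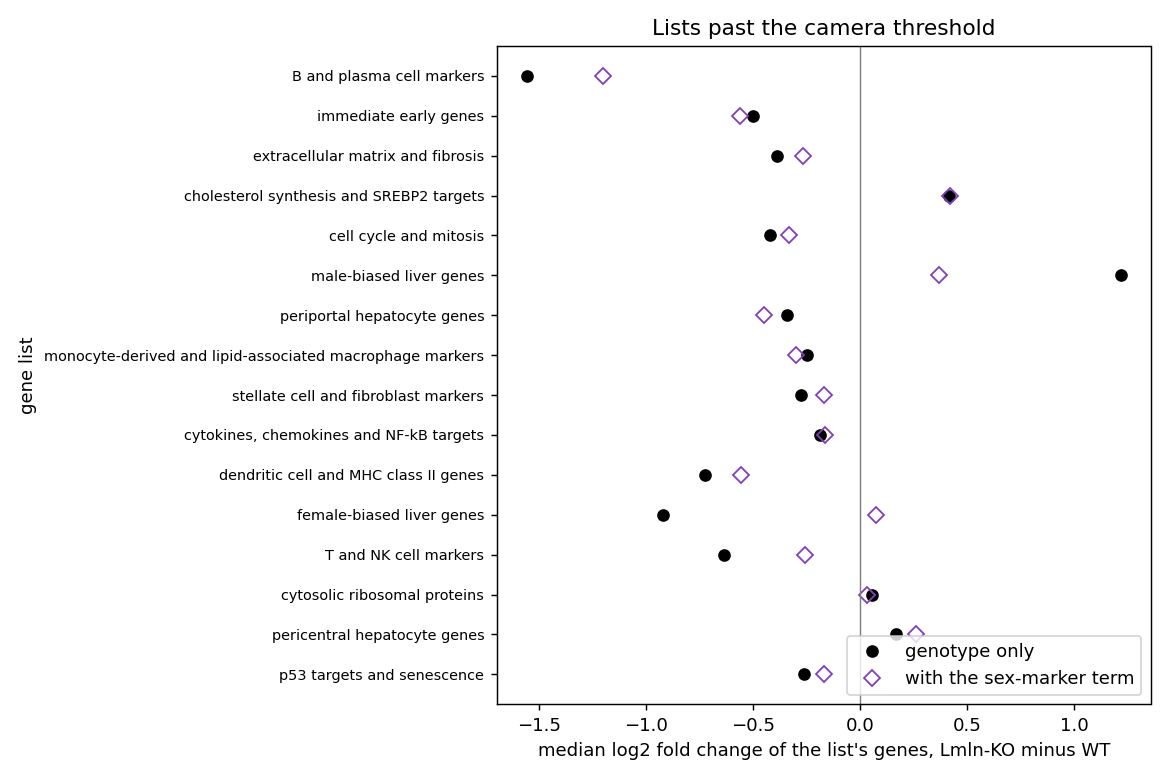
Median log2 fold change (Lmln-KO minus WT) of the 16 lists past the camera threshold at the preset correlation, from the fit by genotype only (filled circles) and with the sex-marker term (open diamonds). The female-biased list moves from -0.92 to 0.07 and the male-biased list from 1.22 to 0.37, while the immediate early list lies at -0.50 and -0.56.

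In all, 16 of 42 tested lists passed camera at the preset correlation, 4 higher and 12 lower, and 12 passed with the sex-marker term, 10 of them shared and in the same direction. The other 2 were the fatty acid oxidation list and the mitochondrially encoded mRNAs, whose median was -0.09 by genotype alone (adjusted p 0.453) and -0.18 with the term (adjusted p 0.007, and adjusted p = 0.739 with an estimated correlation). With an estimated correlation 0 lists passed in either fit, and fry's directional test passed 0. The former test has few degrees of freedom with 6 libraries, so a lost call alone does not show correlated members. By genotype alone the estimates for the 16 lists ran from -0.00482 for immediate early genes to 0.971 for female-biased genes. Other ways of splitting the same 6 libraries, which do not follow genotype, passed between 8 and 18 lists.

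Sequence around a targeted gene can come from another strain, so the neighbours of Lmln were counted apart. Within 10 Mb, 147 genes were tested. DESeq2 called 0 of them, and edgeR called no gene anywhere. At an unadjusted edgeR p under 0.05, 8 of these 147 genes were found (5.44%) and 862 of 18555 elsewhere (4.65%), a difference that a 2-sided Fisher's exact test did not separate (p = 0.557). Within 20 Mb DESeq2 called 1 of 338 genes, the immunoglobulin light chain gene Iglv1 (0.296%, against 0.12% elsewhere, exact p = 0.343), and 22 had an unadjusted edgeR p under 0.05 (6.51%, against 4.62% elsewhere, exact p = 0.116).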

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

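The tests below were chosen after the results were seen. In 8 of 42 lists every Lmln-KO library lay on one side of every WT library among those with Y-linked transcripts and on the opposite side among those with Xist. Libraries without any effect would give 9.33 such lists. The set with Xist has 1 Lmln-KO library, from the 39-week-old animal, and the other set has 1 WT library. A limma test of the difference between the sets passed for 0 of the 42 lists (lowest adjusted p 0.875). The Lmln-KO minus WT difference in mean log2 CPM among the libraries with Xist, less the same difference among those with Y-linked transcripts, was 0.184 for insulin and IGF signalling, 0.225 for bile acid synthesis and transport, -0.47 for NRF2 targets and glutathione, 0.161 for the circadian clock and its output, -0.925 for dendritic cell and MHC class II genes, 0.189 for sinusoidal and vascular endothelial markers, -0.382 for interferon-stimulated genes and -0.324 for iron and heme.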

How the results depend on the processing

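The sex-marker term, its fits with a library left out and the unadjusted count near Lmln were chosen after the data were seen. edgeR called 0 genes under each of the other scalings, the stricter filter, without sex-linked and sex-biased genes, and with the fold-change threshold. limma-voom called 0 with and without weights and with the sex-marker term. DESeq2 called 24 genes (24 lower), DESeq2 with the sex-marker term 31 (4 higher, 27 lower), edgeR with the term 1 (1 lower), and edgeR without a filter 3 (3 lower: Btg2, G6pc and the predicted gene Gm36602, the last named after its value was seen). Leaving out each library gave between 0 and 3 genes (0 to 3 lower, 0 higher); the 3 came without WT replicate 1 and were the immunoglobulin genes Igkc, Ighg1 and Ighv1-26. With the term, leaving out Lmln-KO replicate 3 gave 1 gene, WT replicate 2 gave 4, WT replicate 3 gave 2 and each other library 0. The cause was not tested.

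Lmln stayed lower throughout, from -4.71 to -3.27 with a library left out. DESeq2 gave -3.74 (adjusted p 2.3e-06) and with the term -4.15 (adjusted p 7.13e-08), the fits in which it was called. All 20 named genes kept their direction. They were chosen for having no overlap between the groups, so leaving out a library could hardly reverse them. The count of lists was between 11 and 21 with a library left out, 0 with an estimated correlation, and 0 with the term and an estimated correlation. Of the 16 lists, 6 passed whichever library was left out. The fatty acid oxidation list had medians from -0.25 to 0.27 with a library left out and passed as lower at -0.25 without Lmln-KO replicate 3 and as higher without Lmln-KO replicate 1 (0.15) and WT replicate 2 (0.27). The acute phase list had medians from -0.25 to 0.34 and passed as lower at -0.25 without Lmln-KO replicate 1 and as higher at 0.34 without Lmln-KO replicate 2. The female-biased list had a median of 0.0728 with the sex-marker term, at a preset or an estimated correlation. Lists that did not pass gained a call in 25 cases, among them the interferon list in 5 (all lower, adjusted p down to 1.22e-06 without WT replicate 1) and the amino acid list in 4 (all lower, down to 0.000141 without WT replicate 2). In 48 further cases a list that passed in neither fit changed direction. Near Lmln, 8 genes had an unadjusted p under 0.05.

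Whether the replicate numbers pair the libraries could not be told. The correlation of deviations between same-numbered libraries was 0.465, -0.311 and 0.405, and not every library correlated best with its own number. The sign followed the sex markers in every pair of a Lmln-KO and a WT library, so these values cannot show a pairing or its absence. With the replicate block edgeR called 1 gene (1 lower), Ppp1r3g, and 18 lists passed. The same-numbered libraries 1 and 3 share their sex marker, so this block also takes up part of the sex-marker split.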

Other observations

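The tests of patterns below were chosen after the results were seen. The counts over other splits were laid down before those splits were run. Those with the sex-marker term could be laid down only after the data had been examined. The 5 genes given here were called by DESeq2 with the sex-marker term and chosen after their values were seen. In that fit Igfbp1, an insulin-repressed binding protein, had a log2 fold change of -2.18 (SE 0.286), Per1, a clock gene, one of -0.85 (SE 0.187), and Slc25a25, a mitochondrial carrier, one of -0.67 (SE 0.138). Among the 4 higher genes were Osgin1, an oxidative stress response gene, with 0.81 (SE 0.146), and Cyp7b1, the oxysterol hydroxylase, with 0.70 (SE 0.127). By genotype alone DESeq2 did not call Per1, Slc25a25 or Osgin1 (adjusted p 0.587, 0.0555 and 0.0661). It gave no adjusted p for Igfbp1, with a log2 fold change of -2.41 (SE 1.19), or for Cyp7b1. Cyp7b1 is on the male-biased list, and its log2 fold change of 1.59 (SE 1.30) in that fit also holds the unequal sex mix. None of these 5 passed in edgeR with all 6 libraries, with or without the term.

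The 6 libraries can be split into 3 and 3 in 10 ways. Since edgeR called 0 genes in the real split, all 10 reach that count by construction, which says nothing of chance. The highest other count was 1048, from the split that follows Xist and the Y-linked genes. That split points to the sex-marker structure of the libraries. DESeq2's 24 genes were reached by 3 of 10 splits (highest other 1525), and the 16 lists by 4 of 10 (highest other 18). With the sex-marker term, 9 splits keep the make-up of the groups: 1 edgeR gene or more came from 4 of 9 (highest other 6), 31 DESeq2 genes or more from 3 of 9 (highest other 188), and 12 lists or more from 6 of 9 (highest other 17). So few splits cannot give a share under 0.05.

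For the sex-biased lists, the unequal mix of libraries is a candidate explanation. With the sex-marker term the mean log2 difference of female-biased genes went from -2.10 to 0.0211 (95% interval -0.504 to 0.547), which is consistent with the mix as its source. For male-biased genes it went from 2.05 to 0.390 (0.193 to 0.586), which argues against the mix as the whole cause. Age does not differ among the libraries with Y-linked transcripts, all from 46-week-old animals, where the male-biased median was 0.37. That set rests on a single WT library. Genotype and chance variation between animals stay open, as does age for the libraries with Xist.

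Immediate early genes were lower by a mean log2 difference of -0.672 (95% interval -1.29 to -0.058) with the sex-marker term, against -0.655 without it, which argues against the unequal mix as the cause. A difference in time of day may contribute and cannot be told apart: evening minus morning clock genes differed by 0.285 (-0.294 to 0.865). That score averages evening genes that did not all move together. In DESeq2 with the term Dbp had a log2 fold change of 0.49 (SE 0.144) and Per1 one of -0.85 (SE 0.187). Feeding state may also contribute and cannot be told apart: lipid synthesis minus oxidation genes differed by -0.302 (-0.970 to 0.366). The intervals are too wide to decide. An effect of genotype was not separated from handling of the animals.

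B and plasma cell genes had a mean log2 difference of -1.41 (95% interval -2.86 to 0.0495), and -1.18 (-2.80 to 0.439) with the sex-marker term. The term left most of the difference in place: the list still passed camera at the preset correlation (adjusted p 2.4e-07), and not with an estimated correlation (adjusted p = 0.739). Both intervals hold 0, so the difference was not separated from the spread between libraries. How much of it the unequal mix accounts for cannot be told. Without the 39-week-old animal the mean difference with the term was -0.451 (-2.58 to 1.68), an interval that holds both 0 and the value with that animal. That animal is the 1 Lmln-KO library with Xist, so its age, its genotype and chance variation in a single animal cannot be told apart.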
